A study of Homo sapiens with 2 samples.

How the data were processed

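RNA of 2 cultures of the human melanoma line A375 was compared, 1 with an empty lentivirus and 1 with a lentivirus carrying a BMI1 hairpin. Per the labels' protocols, double-stranded cDNA was made from total RNA with an oligo-dT primer, labelled with Cy3 and hybridised to NimbleGen single-colour expression arrays. The deposited value table holds 1 linear intensity per row and array for 45033 rows, each row named by a sequence accession. The scanner software, the summary of probes into rows and the normalization between arrays are not given in the sources used here. The values were all positive and not logarithmic, from 5.58 to 58812 for the empty vector and from 6.43 to 57881 for shBMI-1. The 2 arrays had close but not identical distributions, with 75th percentiles of 548.7 and 565.0. Detection calls and background values were not used here, so no limit of detection could be set, and with 1 array per group the number of arrays limits the precision.

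Groups were taken from the sample titles. Of the rows, 18188 carried 1 gene symbol in the platform's annotation table, none carried several, and 26845 were unnamed here. Symbols were used as that table gives them. The log2 of each value was taken with no pseudocount and no further normalization. Rows of one symbol were averaged on the log2 scale, which gave 16583 genes, 15297 of them with 1 row and 1286 with 2 or more. A gene passed the brightness limit if it was at or above the median of all rows on at least 1 of the 2 arrays, and 8921 genes passed. Ratios are shBMI-1 minus empty vector on the log2 scale, and their median over these genes was 0.09. No genome was used, and no positions are given.

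With 1 array per group, no test between groups and no p-value was computed, and genes were named by the size of their ratio. The threshold was 2-fold. The rule fixed before the data were examined named BMI1, the 2 PRC1 and the 2 PRC2 components with the largest ratios, the 12 genes with the largest positive and the 12 with the largest negative ratio above the brightness limit, and up to 4 genes of each gene list. The genes taken for the largest ratios needed all rows on one side of 0, and provisional symbols (LOC, FLJ, MGC, KIAA, DKFZ and orf names) and olfactory receptors were left out. Other genes of the lists are named where they are known members, and their values had been seen. The row SD is the pooled SD of the log2 ratios of the rows of one gene, in bands of mean log2 level. In the band of 32 to 64 it rests on 206 genes with several rows and above 4096 on 96.

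A total of 34 gene lists were written before the data were examined, and older symbols in them were replaced by current ones of the RefSeq gene table of GRCh38.p14 where these were unambiguous. For each list with at least 5 genes above the brightness limit, the median ratio was set against 10000 random lists of the same size, drawn without replacement within 10 bins of mean level. A list was counted where its median lay under 2.5% or over 97.5% of the random medians. These percentiles describe these 2 arrays and are not p-values. For 3 lists (CDK inhibitors, fibroblast and endothelial genes) too few genes passed.

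The procedure was tested on simulated data with the observed levels and ratios redrawn among rows of like level with random sign, over 8889 genes for the 2-fold rule and 8690 for the lists. Of 50 genes changed by a log2 ratio of 2, 100% were called 2-fold, and of 50 changed by 1.5, 92%; for -2 and -1.5 the shares were 100% and 86%. The changed genes were drawn from genes with 1 row that passed the brightness limit. Their shares therefore do not cover genes under the limit, such as BMI1. Of the genes that were not changed, 6.13% were also called, because their ratios were drawn from the observed spread. Unchanged lists of 20 genes fell outside the central 95% in 3.5% of 200 cases, and lists raised by 0.3 in 85% of 20 cases.

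Alternatives were centring each array on its median, quantile normalization, loess normalization of the ratio on level (span 0.3, 3 iterations), a pseudocount of 50, the brightest row of each gene, no brightness limit, a limit at the 75th percentile, thresholds of 1.5-fold and 3-fold, list means in place of medians, and 20 level bins. A limit on the mean of both arrays was added after the data were seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 was used.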

Results

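Gene expression was measured in A375, an established human melanoma cell line, on 2 single-colour oligonucleotide arrays. One array held RNA of cells that carried an empty lentivirus, and the other held RNA of cells that carried a lentivirus with a short hairpin RNA against BMI1. BMI1 is a RING-domain subunit of Polycomb repressive complex 1 (PRC1), which represses developmental genes through chromatin. Each group had 1 array, so no value below has a replicate error and no test across samples was possible. Each array gave 45033 values, with a median intensity of 131.2 for the empty vector and 129.8 for shBMI-1. The log2 intensities of the 2 arrays correlated at r = 0.969 across rows, which are not independent replicates. The only error that could be measured was the spread of the ratios of different array rows of one gene, called the row SD here. It was 0.80 on the log2 scale for genes with a mean intensity of 32 to 64, 0.60 at 128 to 256, 0.42 at 256 to 512, 0.25 at 1024 to 2048, and 0.20 above 4096. Rows of one gene can report different transcripts, so the row SD can hold real differences between transcripts as well as error.

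The first comparison asked whether the silenced gene and its partners differed. BMI1 was 2.66-fold lower with the hairpin: its intensity was 68.6 with the empty vector and 25.8 with shBMI-1, a log2 ratio of -1.41. Both values were dim, at the 36.8th and 16.7th percentile of their arrays, so BMI1 lay under the brightness limit used for all other genes. Among the 500 rows closest to it in level, 5.4% had a lower ratio, and the row SD at its level was 0.80. With a pseudocount of 50 the BMI1 log2 ratio was -0.65, short of 2-fold. Per the labels, silencing was also measured by real-time PCR and western blot, which were not analysed here. Of the PRC1 components, 15 passed the brightness limit, and none of them differed by 2-fold. PHC1, a polyhomeotic subunit, was lower (log2 ratio -0.63, row SD 0.25), and CBX7, a chromodomain subunit, was higher (0.60, row SD 0.42). PCGF2, the closest paralog of BMI1, had a log2 ratio of 0.17. The median of the 15 was 0.09, higher than 54.2% of random lists of genes matched on signal level. Of the PRC2 components, which place the methyl mark that PRC1 reads, 8 passed and none differed by 2-fold. JARID2 was lower (-0.86, row SD 0.30), RBBP4 was higher (0.65, row SD 0.30), and the catalytic subunit EZH2 had a ratio of -0.06. The PRC2 median of 0.00 exceeded 20.6% of random lists, its mean was -0.02, and its median was -0.07 after quantile or loess normalization, -0.06 with no brightness limit and -0.05 with the 75th percentile as the limit.

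**Figure D1:**
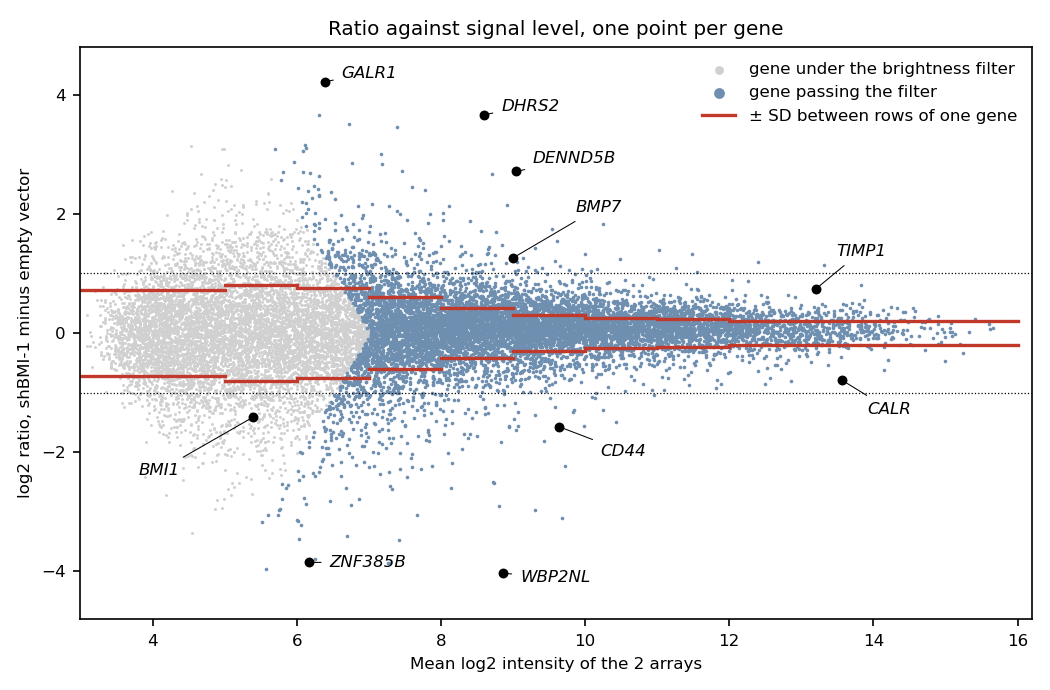
Each point is a gene, with the mean log2 intensity of the 2 arrays on the x axis and the log2 ratio of shBMI-1 to empty vector on the y axis; blue genes passed the brightness limit, grey genes did not, red lines give the SD between rows of one gene at that level and dotted lines mark 2-fold. The row SD falls from 0.80 at intensities of 32 to 64 to 0.20 above 4096, and BMI1, at -1.41, lies in the dim part.

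Known repression targets of Polycomb were examined next. Of the 18 HOX genes above the brightness limit, 13 had a ratio above 0 and 5 below 0, and none reached 2-fold. The median ratio of all genes above the limit was 0.09, so most of them were above 0. Counts above 0 in any list are to be read against that. HOXC8 (0.62, row SD 0.60), HOXD9 (0.56), HOXB9 (0.55; row SD 0.30 for both) and HOXD13 (0.51, row SD 0.42) had the largest ratios. The HOX median of 0.15 exceeded 73.2% of random lists. Among 25 other developmental regulators known as Polycomb targets, 15 were above 0 and 10 below, with a median of 0.10 that exceeded 55.0% of random lists. SIX2 was the only one of them past 2-fold, at 2.57-fold lower, while GATA2 (0.79) and LHX1 (0.82) were above 0 and GATA3 (-0.80) below. Of the CDK inhibitors, only 3 passed the brightness limit, too few for a list value. CDKN1A, a p53-induced inhibitor, was at 6066 and 6239 (0.04 as deposited, -0.02 after loess normalization, -0.01 after quantile normalization and -0.02 in its brighter row). CDKN3 had a ratio of 0.09 and CDKN2D one of 0.40. The INK4 locus genes CDKN2A and CDKN2B, often described as BMI1 targets, were dim on both arrays: CDKN2A averaged 16.5 and 20.2 over 3 rows whose ratios ran from -0.15 to 0.80, and CDKN2B was at 9.93 with the empty vector, with a log2 ratio of 0.71 from 1 row.

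Over the transcriptome, 8921 named genes passed the brightness limit. Of these, 288 were at least 2-fold higher with shBMI-1 and 317 at least 2-fold lower, 6.78% of the genes together. The largest positive ratios were those of GALR1, a galanin receptor (18.6-fold, 19.5 to 362), DHRS2, a short-chain dehydrogenase (12.7-fold, 109 to 1385), and NCMAP, a myelin-associated protein (12.6-fold). TARS3, a threonyl-tRNA synthetase (11.3-fold), SLC22A25, a solute carrier (log2 ratio 3.45), and VAT1L (8.94-fold) followed. The potassium channel gene KCNJ15 was 8.59-fold, RTKN2 8.32-fold, the amino acid transporter gene SLC7A3 7.33-fold, DNASE1 7.26-fold, the fatty acid binding protein gene FABP4 7.15-fold and DENND5B 6.55-fold higher. The largest negative ratios were those of WBP2NL (16.4-fold, 1887 to 115), CAVIN4, a caveolar coat protein (15.5-fold, 187 to 12.1), LRRC52 (14.5-fold) and the hormone gene INSL5 (14.5-fold). ZNF385B was 14.4-fold lower, the nuclear import gene KPNA1 13.8-fold, TH, which encodes tyrosine hydroxylase, 10.9-fold, and ASXL2, a Polycomb-associated gene, 10.6-fold. ARHGAP15 (9.37-fold), TTBK1 (9.05-fold), SCGB1D2 (8.95-fold) and UPK3A (8.84-fold) completed the 12 lowest. The folds and their order rest on dim values: with a pseudocount of 50 all 24 genes stayed past 2-fold, but the log2 ratio of GALR1 was 2.57, below those of DHRS2 (3.17) and SLC22A25 (2.59), and that of CAVIN4 was -1.93.

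All 24 of these genes were measured by 1 row each, and in 23 of them the dimmer array was under its own median, DENND5B being the exception. Of all genes past 2-fold, the dimmer array was under its median in 198 of the 288 higher and 233 of the 317 lower genes. Background values were not used here, so whether the dim values lay above background is unknown. Where 42 genes had a row past 2-fold and at least 1 other row above the brightness limit, the mean of the other rows went the same way in 23. That is 54.8% (exact 95% binomial interval over genes, 38.7% to 70.2%), and that mean was also past 2-fold in 2 genes. The share pools both directions, and agreement was more frequent where the 2-fold row was higher than where it was lower. Among the 3972 genes with both arrays at or above their 75th percentile, 13 were at least 2-fold higher and 9 at least 2-fold lower.

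**Figure D2:**
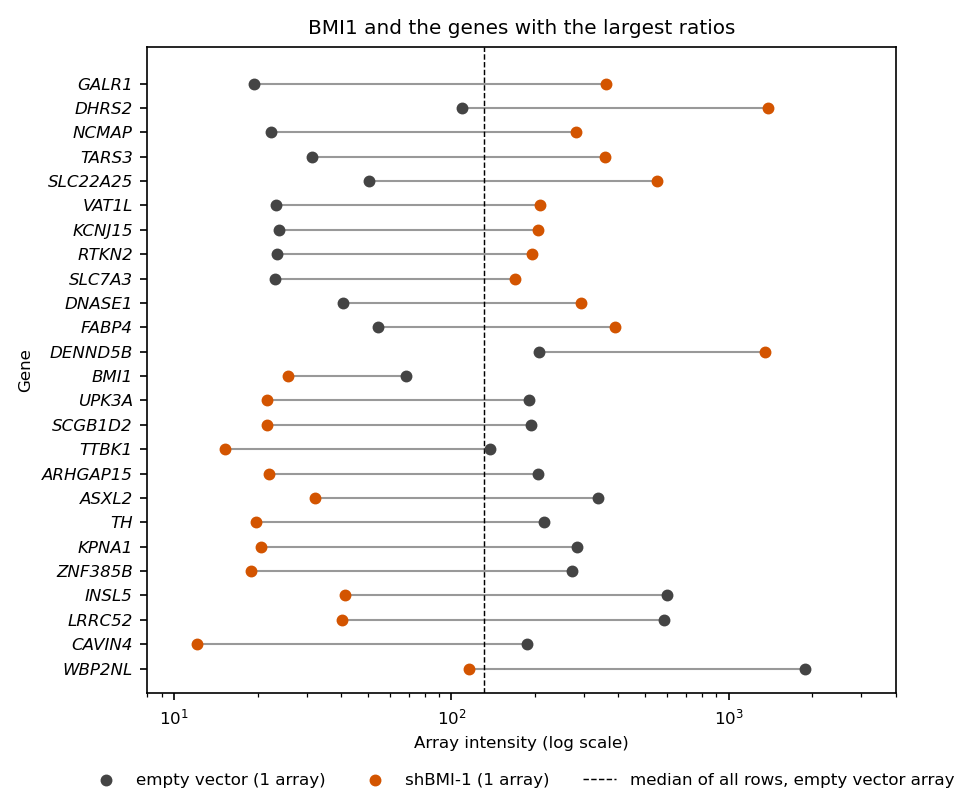
Array intensity on a log axis for BMI1 and the 12 genes with the largest positive and the 12 with the largest negative ratio, with one point per array (grey empty vector, orange shBMI-1), a line joining the 2 arrays, and the median of all rows of the empty vector array dashed. Apart from DENND5B (206 and 1353), each gene has at least 1 array under that array's median.

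Gene lists fixed before the data were examined were then compared with 10000 random lists of equal size and signal level. Of 31 lists with at least 5 measured genes, 3 had a median outside the central 95% of their random lists, all above, where about 1.55 would fall outside by construction. Interferon-stimulated genes had a median log2 ratio of 0.26, above 98.7% of random lists, with 14 of 21 genes above 0. XAF1, a pro-apoptotic interferon-induced gene, was 2.37-fold higher (124 to 295, row SD 0.60; log2 ratio 0.98 with a pseudocount of 50), and MX1 (0.70), IRF9 (0.64) and BST2 (0.56) were above 0. The RNA sensor gene RIGI (-0.72) and ISG20 (-0.39) were below 0. The 3 rows of OAS1 ran from -1.26 to 0.42. This list's place depended on the brightness limit: its median exceeded 26.1% of random lists with no limit and 37.9% with the 75th percentile as the limit. Without XAF1 it exceeded 97.0%, after quantile normalization 97.1%, and by its mean 95.3%.

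Genes of the unfolded protein and amino acid stress responses had a median of 0.23, above 97.8% of random lists, with 17 of 23 genes above 0. DDIT3, a stress-induced transcription factor, was 2.93-fold higher (55.7 to 163, row SD 0.76). SESN2 (0.80, row SD 0.42) and ASNS, asparagine synthetase (0.68, row SD 0.25), were also above 0. The calcium-binding chaperone gene CALR was lower, from 16002 to 9223 (-0.79, row SD 0.20), and the main endoplasmic reticulum chaperone gene HSPA5 had a ratio of 0.24. Without DDIT3 the median exceeded 95.01% of random lists. The list also fell short of the upper limit with the brightest row of each gene (88.5%), by its mean (92.0%), with a pseudocount of 50 (94.5%), and with a brightness limit on the mean of both arrays (95.5%) or at the 75th percentile (96.0%). Cancer-testis antigens, germline genes expressed by many melanomas, had a median of 0.23, above 98.8% of random lists, with 18 of 22 genes above 0. PAGE1 (2.44-fold, 97.3 to 237) and SPANXC (log2 ratio 1.14) were past 2-fold as deposited but not with a pseudocount of 50 (0.96 and 0.79), and SSX2 (0.63 over 2 rows), MAGEA10 (0.51 over 2 rows), MAGEA1 (0.47) and MAGEA4 (0.39) were above 0. PAGE2 was below 0 (-0.27). Many of these genes have near-identical copies, so their signals are uncertain as separate measurements, and with the 75th percentile as the limit the list exceeded 95.1% of random lists.

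**Figure D3:**
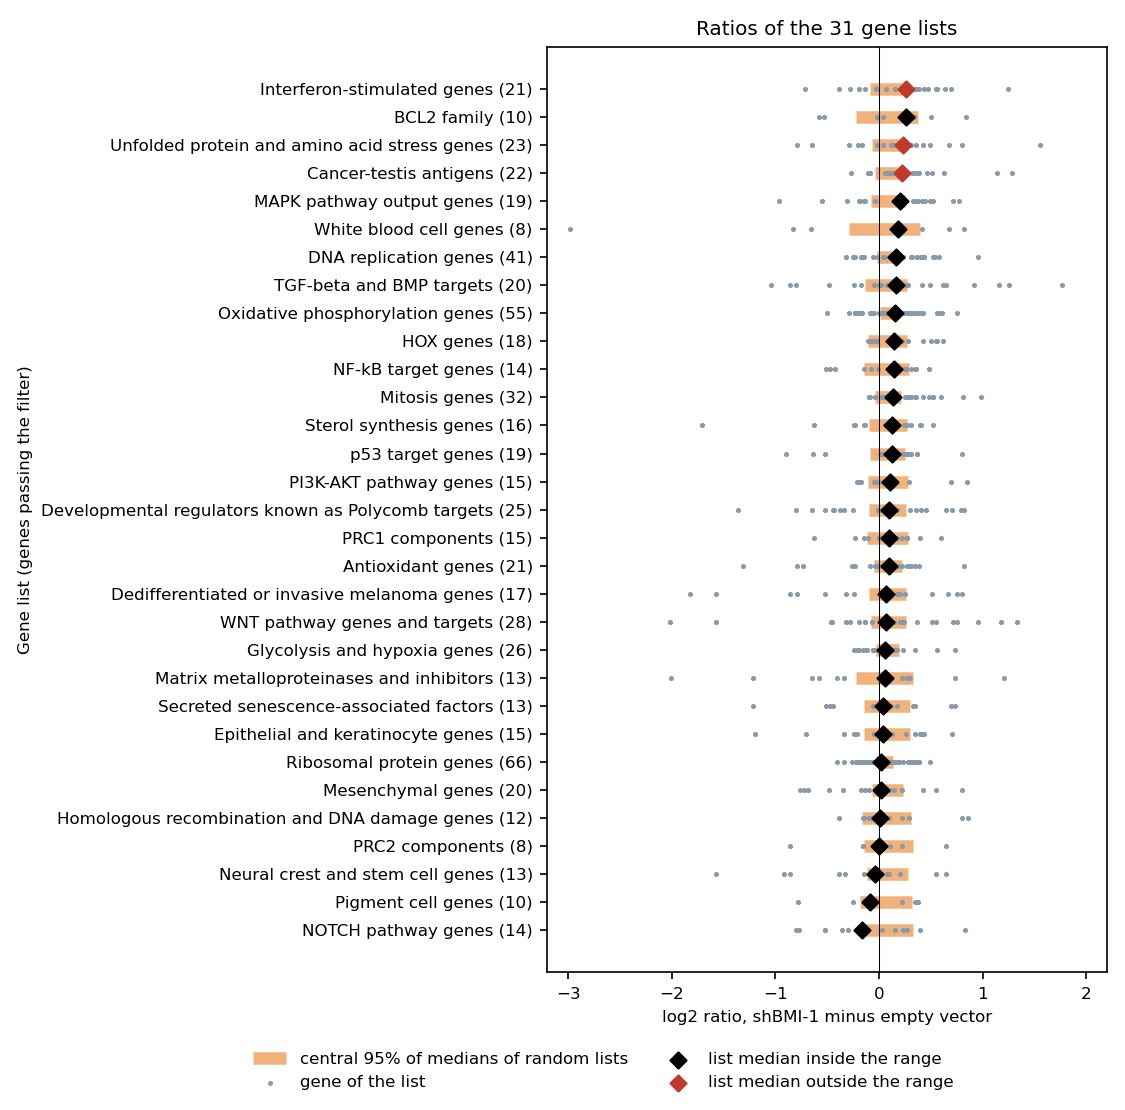
Log2 ratios of shBMI-1 to empty vector for the genes of 31 lists (dots), the median of each list (diamonds) and the central 95% of medians of random lists matched on signal level (bars). The medians of the interferon-stimulated (0.26), stress response (0.23) and cancer-testis (0.23) lists lie just above their bars.

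The medians of the other lists lay within their random ranges. Medians near 0 depended on scaling: those of the secreted senescence, mesenchymal, epithelial and DNA damage lists were below 0 after quantile or loess normalization, that of the glycolysis list after quantile normalization, and those of the WNT and ribosomal lists after loess normalization. With the brightest row of each gene, the pigment cell median was above 0 (0.09) and the epithelial (-0.003) and metalloproteinase (-0.16) medians were below 0. Among proliferation genes, mitosis genes had a median of 0.14 (above 79.1% of random lists, 28 of 32 genes above 0) and DNA replication genes one of 0.17 (93.7%, 33 of 41 above 0). No gene of either list reached 2-fold. The spindle and cytokinesis genes ANLN (0.99) and ASPM (0.81) and the primase subunit gene PRIM2 (0.95) had the largest ratios, each with a row SD of 0.60. The replication list passed the upper limit after loess normalization (98.1%), quantile normalization (98.1%) and by its mean (99.3%). The mitosis list stayed short of it, at 90.2% after quantile normalization and 97.2% by its mean of 0.23. The DNA damage list had a median of 0.01 (27.8%), with CHEK1 (0.80, row SD 0.30) and H2AX (0.86, row SD 0.25) above 0. Its median was 0.07 (55.2%) over 25 genes with no brightness limit and 0.22 (77.9%) over 5 genes with the 75th percentile as the limit, and its mean was 0.12 (68.4%). The p53 targets had a median of 0.12 (67.2%), with 16 of 19 genes above 0, among them SESN2. Such counts say little alone, since most of all genes above the brightness limit were above 0. The 3 genes below 0 included GADD45A (-0.90) and PLK2 (-0.64). The BCL2 family had a median of 0.26 over 10 genes (88.6%), with BOK at 0.84 and BCL2 at -0.58.

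Genes that mark melanoma cell states gave mixed values. The dedifferentiated or invasive list had a median of 0.07 (42.4%) and a mean of -0.15, with 2 genes past 2-fold, both lower. PDGFRB, a growth factor receptor, was 3.53-fold lower (427 to 121), and CD44, a hyaluronan receptor, was 2.97-fold lower (1373 to 462, row SD 0.30). NGFR, a neural crest receptor, was 1.81-fold lower (2414 to 1332, row SD 0.25), and FN1 was 1.74-fold higher, with its rows at 0.61 and 0.98. The neural crest and stem cell list had a median of -0.04 (9.46%), with 6 of 13 genes above 0, among them TFAP2A (0.65), and 7 below, among them CD44, KLF4 (-0.91) and NGFR. Among genes with the 75th percentile as the brightness limit, the invasive list exceeded 0.64% and the neural crest list 0.08% of random lists; these lists share CD44 and NGFR among others. The pigment cell list had a median of -0.08 over 10 genes (10.4%), but of 0.22 (86.2%) with the 75th percentile as the brightness limit, 0.08 (51.2%) with a limit on the mean of both arrays and 0.03 (42.8%) with no limit. SLC24A5, a melanosomal ion exchanger, had a ratio of -0.78. SOX10 had a ratio of -0.14 at an intensity near 7608 with the empty vector, while MITF, TYR and MLANA were under the brightness limit on both arrays. Mesenchymal genes had a median of 0.02 (20.7%) and a mean of -0.05, with COL5A1 (-0.76) and COL6A3 (-0.72) below 0. Matrix metalloproteinases and their inhibitors had a median of 0.05 (47.0%), a median of -0.02 with no brightness limit, and a mean of -0.18. MMP7 (4.01-fold) and MMP3 (2.32-fold) were lower, MMP15 was 2.30-fold higher, and TIMP1 was 1.67-fold higher (7280 to 12135, row SD 0.20). With a pseudocount of 50, MMP3 (-0.79) and MMP15 (0.996) were short of 2-fold and the log2 ratio of MMP7 was -1.14.

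In signalling pathways, the TGF-beta and BMP list had a median of 0.17 (81.7%). The ligand genes BMP6 (3.39-fold, 42.9 to 146, row SD 0.76), BMP7 (2.39-fold) and BMP2 (2.23-fold) were higher, and TGFB3 was 2.06-fold lower. With a pseudocount of 50, BMP2 (0.93) and TGFB3 (-0.75) were short of 2-fold and the log2 ratio of BMP6 was 1.07. With the 75th percentile as the brightness limit this list exceeded 98.9% of random lists, and with no limit it exceeded 54.5% (median 0.08). The WNT list had a median of 0.07 (39.0%), and of 0.12 (67.0%) with a limit on the mean of both arrays, with DKK4 (2.52-fold) and FZD1 (2.25-fold) higher and WNT5B (4.04-fold) and CD44 lower. With a pseudocount of 50, DKK4 was short of 2-fold (0.97) and the log2 ratio of WNT5B was -1.15. NOTCH genes had the lowest median, -0.16 (3.28%), which was 0.02 (42.9%) over 29 genes with no brightness limit, with RBPJ (-0.77, row SD 0.30) and DTX3L (-0.80) below 0 and NUMB (0.83) above. MAPK output genes had a median of 0.20 (92.7%), but of -0.08 (2.65%) with no brightness limit and -0.04 (5.88%) with the 75th percentile as the limit. The feedback inhibitor gene SPRY4 was 1.65-fold higher (3263 to 5370, row SD 0.20), while SPRED1 (-0.97) and SPRY2 (-0.55) were below 0. PI3K-AKT genes had a median of 0.11 (55.9%), with FOXO4 at 0.85 and MTOR at 0.69. NF-kB targets had a median of 0.14 (69.9%), with RELB at 0.48 and CXCL2 at -0.52. Secreted senescence-associated factors had a median of 0.04 (34.3%), a median of 0.11 (74.2%) over 29 genes with no brightness limit and a mean of -0.02, with MMP3 below 0 and TIMP1 and IGFBP7 (0.70) above.

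Metabolic lists were within their random ranges as well. Oxidative phosphorylation genes had a median of 0.16 (95.02%, 42 of 55 genes above 0), with NDUFA6 at 0.75 and NDUFS8 at 0.61. Glycolysis and hypoxia genes had a median of 0.06 (34.8%), with ENO2 1.66-fold higher (2193 to 3641, row SD 0.23). Antioxidant genes had a median of 0.09 (56.4%) and a mean of -0.01; AKR1B10 was 2.48-fold lower (log2 ratio -0.92 with a pseudocount of 50) and GSR was 1.76-fold higher. Sterol synthesis genes had a median of 0.12 (66.7%) and a mean of -0.02, with 10 genes above 0 and 6 below. HMGCS1 was 3.26-fold lower in 1 row (215 to 65.7, row SD 0.76), with a log2 ratio of -1.19 with a pseudocount of 50. SREBF2 (-0.63) was also below 0, and HSD17B7 (0.52) and INSIG1 (0.41) were above. Ribosomal protein genes had a median of 0.02 (7.42%), and their ratios ran from -0.40 for RPS27 to 0.49 for RPL27A.

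Markers of other cell types gave values on both sides of 0. White blood cell genes had a median of 0.18 over 8 genes (76.1%) and a mean of -0.27; LAPTM5 was 7.88-fold lower (152 to 19.3; log2 ratio -1.54 with a pseudocount of 50), CD68 was 1.59-fold higher, and PTPRC was dim on both arrays (12.9 and 12.3). Epithelial and keratinocyte genes had a median of 0.04 (32.6%), a median of 0.12 (75.1%) over 31 genes with no brightness limit and a mean near 0 (-0.005), with ST14 2.29-fold lower (log2 ratio -0.88 with a pseudocount of 50) and SFN at 0.70. Only 1 fibroblast marker, PDGFRB, and 4 endothelial markers passed the brightness limit, among them TIE1 at -0.84 and ENG at -0.02. With no brightness limit the fibroblast median was -0.38 (3.61%) over 15 genes, nearly all of them dim. The endothelial median was then -0.06 (29.4%) over 15 genes.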

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

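The comparison between rows of one gene and the bounds for reading the loess count were chosen after the results were seen, while loess normalization itself was planned. Rows without a gene name here were outside the gene comparisons and also differed between the arrays: of 14184 such rows above the brightness limit, 467 were at least 2-fold higher and 534 at least 2-fold lower with shBMI-1. That is 7.06% of them, against 6.78% of the named genes. Among the 6059 unnamed rows with both arrays at or above their 75th percentile, 11 were at least 2-fold higher and 20 at least 2-fold lower.

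The 2-fold differences as a whole, 288 higher and 317 lower named genes, were weighed against 2 technical explanations. A shift of the centre of the ratios with signal level is argued against as the cause of the counts. After loess normalization 602 genes were still past 2-fold, 262 of the 288 higher and 315 of the 317 lower ones among them. Loess normalization leaves the spread of the ratios, which was wider in dim genes, so the counts can still depend on level. The SD of the ratios of all named rows was 0.87 at intensities of 32 to 64 and 0.23 above 4096. Error of single array rows remains open as a cause of the 2-fold differences. The mean of the other rows of a gene with a 2-fold row went the same way in 54.8% of 42 genes. Agreement was more frequent where the 2-fold row was higher than where it was lower, and the directions were not tested apart. The median ratio of all genes above the brightness limit was 0.09, so the ratios were not centred on 0. Unrelated rows would give about equal shares of both directions. Among rows bright on both arrays the other rows went the same way in 3 of 3 genes, too few to decide. In dim genes the row SD was close to the SD of all named rows, so much of the spread lay between rows of one gene. It was 0.80 against 0.87 at 32 to 64 and 0.60 against 0.65 at 128 to 256. At 1024 to 2048 it was 0.25 against 0.31. Row error alone is harder to set beside smaller differences, since 23 of 619 genes with several rows had every row at least 0.5 from 0 on the same side, against 11 on average and at most 23 in 1000 random deals of the rows, though errors shared between rows were not tested. Transcripts of one gene that respond differently stay open, as does an effect of BMI1 silencing, because 1 array per group separates the latter neither from this error nor from differences between 2 cultures.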

How the results depend on the processing

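With 1 array per group no replicate could be left out, and no paired analysis was possible because each group has 1 array. The counts of 288 higher and 317 lower genes stayed within 1.5 times of these values under median centring (300 and 310), quantile normalization (275 and 331), loess normalization (265 and 337) and the brightest row of each gene (304 and 342). They were 142 and 190 with a pseudocount of 50, 883 and 917 with no brightness limit, 47 and 51 with a limit at the 75th percentile, and 153 and 163 with a limit on the mean of both arrays. A threshold of 1.5-fold gave 901 and 754, and one of 3-fold gave 80 and 132. BMI1 had a log2 ratio of -0.65 with the pseudocount, which shrinks the ratios of dim genes by construction, and stayed past 2-fold under the other scalings. The number of lists outside their random range stayed between 2 and 4, but the lists varied. The median of the interferon list exceeded 26.1% of random lists with no brightness limit and 37.9% with the 75th percentile as the limit; the first adds dim genes and the second leaves 11 genes, and the cause was not tested further. Of the ratios of single named genes other than BMI1 under other scalings, 720 kept their direction and their side of 2-fold, 10 fell under it, all with the pseudocount (MMP3, XAF1, ST14, DKK4, BMP2, TGFB3, MMP15, AKR1B10, PAGE1 and SPANXC), 1 (ANLN) passed it and 3, all of CDKN1A near 0, changed sign. Of the list percentiles, 291 stayed on their side of the limits, 8 no longer passed, 6 newly passed, and 2, those of the interferon list given above, no longer passed and also went from above to below the middle of their random lists, with medians still above 0. Part of these tallies was fixed by construction. Centring each array on its median shifts all ratios alike and left every list percentile unchanged. For a gene with 1 row, the brightest row is its only row. No background measure was used here, so how far signal over background limits the dim genes is unknown.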

Other observations

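The test of other BMP-responsive genes was fixed before its median was seen. Of its measured genes, HEY1, DLX2 and MSX1 were also in gene lists already scored, so it was not blind to their ratios. Loess normalization was planned, and the other tests in this part were chosen after the results were seen. For the gene lists, the rules for reading the loess and the cancer-testis tests were also set after their values were seen. The loess values are given for each list separately. Genes that were bright on both arrays and past 2-fold give the values least exposed to dim signal; they were picked after their values were seen and each had 1 row. Among the higher genes were DNMT3L, a regulator of DNA methyltransferases (3.54-fold, 649 to 2299), EPS15L1 (2.62-fold), NEFL, the neurofilament light chain (2.52-fold), the ascorbate transporter gene SLC23A1 (2.49-fold), CAPS (2.27-fold, 3585 to 8155) and SERPINA3, a secreted protease inhibitor (2.22-fold, 6866 to 15236). The row SD at their levels was 0.25 for DNMT3L and NEFL, 0.23 for EPS15L1 and SLC23A1, and 0.20 for CAPS and SERPINA3. Among the lower genes were NBPF3 (2.96-fold, 1751 to 591), which belongs to a family of near-identical copies, SUSD2 (2.81-fold, 2310 to 822), THAP12 (2.51-fold), ZNF276 (2.46-fold), ESD (2.44-fold) and the autophagy gene AMBRA1 (2.12-fold).

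Genes with several rows that all went one way give a second view. Of 619 genes with all of their 2 or more rows above the brightness limit, 23 had every row at least 0.5 from 0 on the same side, 17 higher and 6 lower. Dealing the rows out at random within 10 bins of level gave 11 such genes on average, and the highest of 1000 deals gave 23. Higher in both rows were SLC22A17 (3.75-fold), the kallikrein gene KLK6 (2.23-fold), FEZ1 (2.03-fold), the fatty acid import gene CPT1A (1.89-fold), the matrix gene ECM1 (1.84-fold, 3600 to 6628) and FN1 (1.74-fold). Lower were the calcium-binding protein gene CALB2 (2.43-fold over 2 rows), CLCN3 (2.17-fold over 2 rows), FBLN1 (1.71-fold over 4 rows) and the growth factor gene MDK (1.58-fold over 3 rows). With a pseudocount of 50, FEZ1 (log2 ratio 0.82) and CLCN3 (-0.82) were short of 2-fold and SLC22A17 was at 1.19. Whether the rows of a gene share probes is not stated in the sources used here.

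The 3 gene lists above their random ranges may be chance among the lists scored. Random families of 31 lists held as many lists outside their ranges in 19.1% of draws, so chance is not argued against. The random lists were matched on level, so a trend of the ratio with level was already largely taken out of the list percentiles. Loess normalization removes that trend again, could therefore move the percentiles little, and does not decide the question. After it the stress and cancer-testis lists exceeded 98.8% and 98.9% of random lists. The interferon list then exceeded 97.6%, within the error of 10000 draws of the upper limit. For cancer-testis genes, signal shared between near-identical copies cannot be told apart from separate changes: with the brightest member of each of 7 families the median stayed at 0.23, but it then exceeded 88.6% of random lists, since 7 genes vary more than 22.

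A hypothesis from the values is a response to BMP ligands. BMP2, BMP4, BMP6 and BMP7 had log2 ratios of 1.16, 0.92, 1.76 and 1.26, the BMP-induced genes ID1, ID2 and ID3 had 0.49, 0.65 and 0.61, and the BMP antagonist gene NOG had -0.86; with a pseudocount of 50, BMP2 was at 0.93 and BMP6 at 1.07. BMP6 was dim with the empty vector (42.9, against 146 with shBMI-1) and passed the brightness limit through the shBMI-1 array only. Over the 7 BMP and ID genes the ratio was 2.19 times the row SD at the median. These 7 genes were picked for their ratios, so this does not exclude row error. ID4, SMAD6, SMAD7 and BAMBI, also in the TGF-beta and BMP list, were neither among these 7 genes nor among the 18 that follow. Their ratios are not given here, so the 7 picked genes do not stand for the TGF-beta and BMP list. The median of that list, 0.17, exceeded 81.7% of random lists, inside its random range. Of the 20 measured genes of that list, 12 were above 0 and 8 below. Of 18 other BMP-responsive genes, 7 passed the brightness limit, 5 of them above 0, with HEY1 at 0.27, ATOH8 at 0.29 and JUNB at 0.40, and ALPL at -0.54. Their median of 0.29 exceeded 89.3% of random lists, between the bounds set for and against the hypothesis, which therefore stays open.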
